A study of Homo sapiens with 82 samples.

How the data were processed

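The series covers 82 samples of 2 human cell lines, of which the 75 RNA-seq libraries were analysed and the 7 ChIP-seq samples (2 inputs, and H3K27ac in 2 knockout and 3 wild-type samples) were not analysed here. Per the labels, RNA libraries were made with the QuantSeq 3′ kit of Lexogen. Set 1 holds 39 libraries of U2OS: 13 time points from 0 to 48 h, 4 h apart, in a control and in the ADIRF-AS1 knockout clones E2 and H9. Sets 2, 3 and 4 hold 36 libraries of 786-O in 12 groups of 3. The deposited values are expected counts per gene, and per the submitters' processing notes they were made with Bowtie2, RSEM 1.2.3 and the genome build hg19, with DESeq2 named as well. The notes do not state the role or order of these tools, the gene annotation, the use of strand or the counting settings. All values in the table (100%) were whole numbers, so rounding changed nothing. The table holds 57736 gene identifiers, of which 51959 carry a symbol, and all 75 columns matched a label. Totals ran from 5.15 to 11.8 M in U2OS and from 10.99 to 19.3 M in 786-O, and U2OS libraries of 0 to 24 h were shallower (median 5.66 M) than those of 28 to 48 h (8.56 M). The 10 most abundant genes took 3.98 to 6.74% of counts in 786-O and 4.99 to 6.91% in U2OS.

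Genes were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests on TMM-scaled counts, after filterByExpr on the design, and called at a Benjamini-Hochberg adjusted p under 0.05. Each set of 786-O was fitted by itself, with all its groups sharing 1 estimate of spread. In set 4 the double knockout was the mean of c5 and c47, and the interaction was that mean minus c17 minus the PBRM1 knockout plus the control. The test across clones summed the 3 libraries of each group and used set as a covariate, so that the 6 clones were the replicates. U2OS was fitted with time as a factor and a term for each clone, and the mean of E2 and H9 was tested. Rhythms were tested in each U2OS line with a cosine and sine of 24 h and a linear trend, and differences in rhythm by the terms of the clones. Amplitudes are log2 and peaks are in hours. CPM are counts scaled to library size, with TMM factors beside tests, and levels compared between sets are of library totals. Standard errors are those of the log2 fold change. Where a group had 0 counts the fold is a floor, with 3 counts put in for the group. With 3 libraries against 3 the smallest exact p is 0.1, and 10% of genes would show no overlap by chance.

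The 29 gene lists were written before the files were opened: core clock, G2/M, S phase, HIF, p53, NF-kB, NRF2, TGF-beta and YAP, integrated stress and unfolded protein responses, immediate early, interferon-stimulated, antigen presentation, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, histone, SWI/SNF, collagen, matrix glycoprotein, matrix enzyme, integrin and cadherin, metallothionein, epithelial to mesenchymal, renal epithelial, osteoblast, leukocyte and endothelial genes, and neighbours of the ADIRF-AS1 locus. They were tested with camera of limma 3.58.1 at the preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Gene order came from a RefSeq table of GRCh38.p14, which is not the build of the counts, so only names and order were used and no coordinates are given. Named genes followed a rule written before the files were opened: ADIRF-AS1, ADIRF and PBRM1 always; the 6 largest rises and 6 largest falls per comparison among called genes with an average of at least 10 CPM and no overlap between groups; up to 4 called members per list; and for rhythms the core clock and the 8 genes with the smallest adjusted p. Others are named as chosen after their values were seen.

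Alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, limma-voom, no filter beyond 1 count, a filter of 10 CPM, leaving out each library or set, a block for replicate number, and, in U2OS, no time term, a harmonic in place of the time factor, periods of 22 and 26 h, no trend, and no libraries before 12 h. Chosen after the data were seen were leaving out the 3 libraries that stand apart, the mean rhythm of the 3 lines, and time as a shared factor in the rhythm difference. The scripts were tested on simulated counts with 200 genes changed. For the PBRM1 knockout (15112 genes) 29.9% were called at 1.5-fold, 91.0% at 2-fold and 100% at 4-fold, with 9 false calls. Across clones (17939 genes) the shares were 10.4%, 71.6% and 98.5%, and in U2OS (15759 genes) 71.6% at 1.2-fold and 100% at 1.5-fold. The lowest ratio of chi-square to degrees of freedom between replicates of 786-O was 2.31, above the value of 1 that counting error alone gives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.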

Results

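RNA was measured in 75 libraries of human cell lines by 3′-end sequencing, in which each transcript gives a tag near its poly(A) tail. The labels set the subject: knockout of ADIRF-AS1 (ENSG00000272734), a long noncoding RNA lying antisense to the adipogenesis gene ADIRF (ENSG00000148671), and of PBRM1 (ENSG00000163939), a subunit of the chromatin remodeller PBAF. U2OS, an osteosarcoma line much used in circadian work, was sampled every 4 h from 0 to 48 h in a control line and in the knockout clones E2 and H9, with 1 library per line and time point (13 per line). 786-O, a clear cell renal carcinoma line that lacks working VHL, came in sets 2, 3 and 4, each with its own control and 3 libraries per group. Set 2 held the ADIRF-AS1 knockout clones c4 and c7, set 3 the clones c23, c36 and c41, and set 4 the clone c17, a PBRM1 knockout and the double knockout clones c5 and c47. The labels do not say whether the 3 libraries of a group came from separate cultures, so they may be technical replicates. Libraries held 5.15 to 11.8 M counts in U2OS (median 6.82 M) and 10.99 to 19.3 M in 786-O (median 13.5 M). In 3 libraries of 786-O the SD of log2 deviations from the group mean passed 0.4: set 3 control 1 (0.436), c36 replicate 3 (0.565) and set 4 control 2 (0.559).

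ADIRF-AS1 RNA was lower in every knockout clone of both lines, and ADIRF messenger RNA fell with it in 8 of 10 clones. In U2OS, ADIRF-AS1 averaged 4.31 ± 2.4 CPM (counts scaled to library size) in the control (SD, n = 13), 0.206 ± 0.16 in E2 and 0.198 ± 0.26 in H9, a log2 fold change of -4.34 ± 0.31 (SE; edgeR adjusted p = 4.0e-13). In 786-O it fell from 2.317 ± 0.35 in the set 2 control to 0.765 ± 0.15 in c4 and 0.479 ± 0.30 in c7, from 3.68 ± 0.32 in the set 3 control to 0.194 to 0.426 in the 3 clones, and from 1.90 ± 0.48 in the set 4 control to 0.0905 in c17, 0.422 in c5 and 0.200 in c47 (n = 3 each). The share of ADIRF-AS1 that remained ran from 4.70% in E2 to 32.5% in c4. ADIRF was at 0 counts in all 3 libraries of c41, c17 and c47, at least 26.1-fold, 23-fold and 26.9-fold lower than in their controls, and in U2OS it fell by 6.19 ± 0.30 log2 units. It was not called in c4 (-2.14, edgeR adjusted p = 0.101) or c23 (-0.62, 0.486), where c23 kept 62.3 ± 17.4% of its ADIRF and 11.1 ± 4.1% of its ADIRF-AS1. The PBRM1 knockout alone left ADIRF-AS1 uncalled (1.56 ± 0.52 against 1.90 ± 0.48, -0.28 ± 0.50, edgeR adjusted p = 0.700). Strand use in counting is not stated, so how far reads of the overlapping genes ADIRF-AS1 and ADIRF were mixed is not known. The floors given here for genes at 0 counts cover counting error only. The intervals are SDs between libraries or standard errors.

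**Figure D1:**
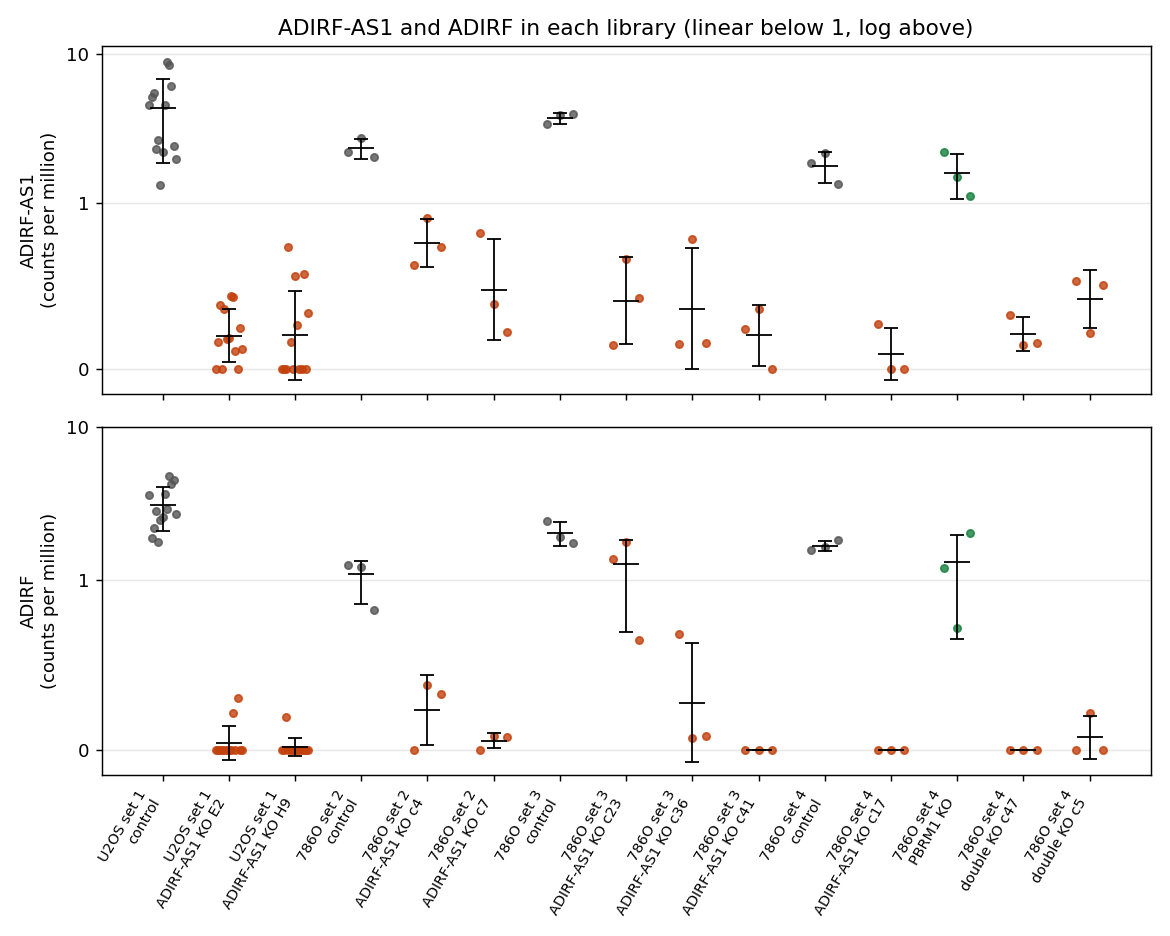
ADIRF-AS1 and ADIRF CPM in each library, with group mean ± SD. ADIRF-AS1 kept 4.70% of its control level in E2 and 32.5% in c4, and ADIRF was at 0 in c41, c17 and c47.

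PBRM1 messenger RNA stayed near its control level in the cells labelled PBRM1 knockout. It averaged 53 ± 2.1 CPM against 63.7 ± 5.9 in the set 4 control (n = 3 each; log2 fold change -0.27 ± 0.10, edgeR adjusted p = 0.042), and the double knockouts split, with PBRM1 at -0.82 in c5 and 0.04 in c47. A 3′ tag of PBRM1 lies outside any frameshift made upstream, so this level checks nothing about the protein. PBRM1 RNA was higher in the ADIRF-AS1 clones of set 3 (0.67 in c23, 0.55 in c36 and 0.63 in c41, from 34.6 ± 2.2 in their control) and was not called in c4, c7 or c17. The set 3 control stood below the other controls. By library total its libraries had 32.3 to 37.9 CPM of PBRM1, against 99.7 to 110 in the set 2 control and 52.2 to 66.1 in the set 4 control. The difference in set 3 may thus belong to its control.

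The controls of the 3 sets of 786-O differed widely from one another, in genes that include those most changed by knockout. HIF1A, the hypoxia-inducible transcription factor, stood at 173 ± 14 CPM of library total in the set 4 control and between 4.26 ± 0.36 and 12.0 ± 0.53 in the other 11 groups, the controls of sets 2 and 3 among them (n = 3 each). The potassium channel partner KCNIP1 was at 53 ± 12 in the set 4 control and at most 0.19 ± 0.11 elsewhere, and the metal-binding protein MT1E was at 151 ± 44 there against 787 ± 46 and 602 ± 119 in the controls of sets 2 and 3. The collagen chain COL6A3 was at 84.1 ± 21 in the set 4 control and between 2.1 and 16.1 in the other groups. In set 3, PLXDC2 had no counts in the control, 26.3 to 46.6 in its clones, and 29.6 ± 3.0 and 32.5 ± 4.3 in the controls of sets 2 and 4. The kinase subunit PRKAA2 was at 0.162 ± 0.18 in the set 3 control against 35.1 and 28.6 in the controls of sets 2 and 4. The chromatin organiser SATB1 was at 0.02 in the set 3 control and 26.7 to 30.3 in its clones, with 21.1 in the set 4 control and 4.25 in the set 2 control. In set 3, 551 of 15360 genes lay more than 2-fold off the control in the same direction in all 3 clones, and for 321 of them (58.3%) the set 2 control was nearer to the knockouts than to the set 3 control. The set 4 control was nearer to them for 366 (66.4%). In set 4, 547 of 15448 genes were shared in this way by all 4 knockout groups, and the set 2 control was nearer to the knockouts for 428 (78.2%) and the set 3 control for 294 (53.7%). Both other controls were nearer to the knockouts for 236 (42.8%) of the genes of set 3 and 251 (45.9%) of those of set 4. Other genes went another way: USH1C was at 1.04, 0.02 and 0.72 in the controls of sets 2, 3 and 4 and at 20.4 to 26.6 in the set 3 clones alone, and LCP1 was at most 6.82 in the controls and 71.5 to 476 in the groups with PBRM1 knocked out. The genes were chosen after their values were seen, and the counts were planned after the levels of some of them had been seen.

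**Figure D2:**
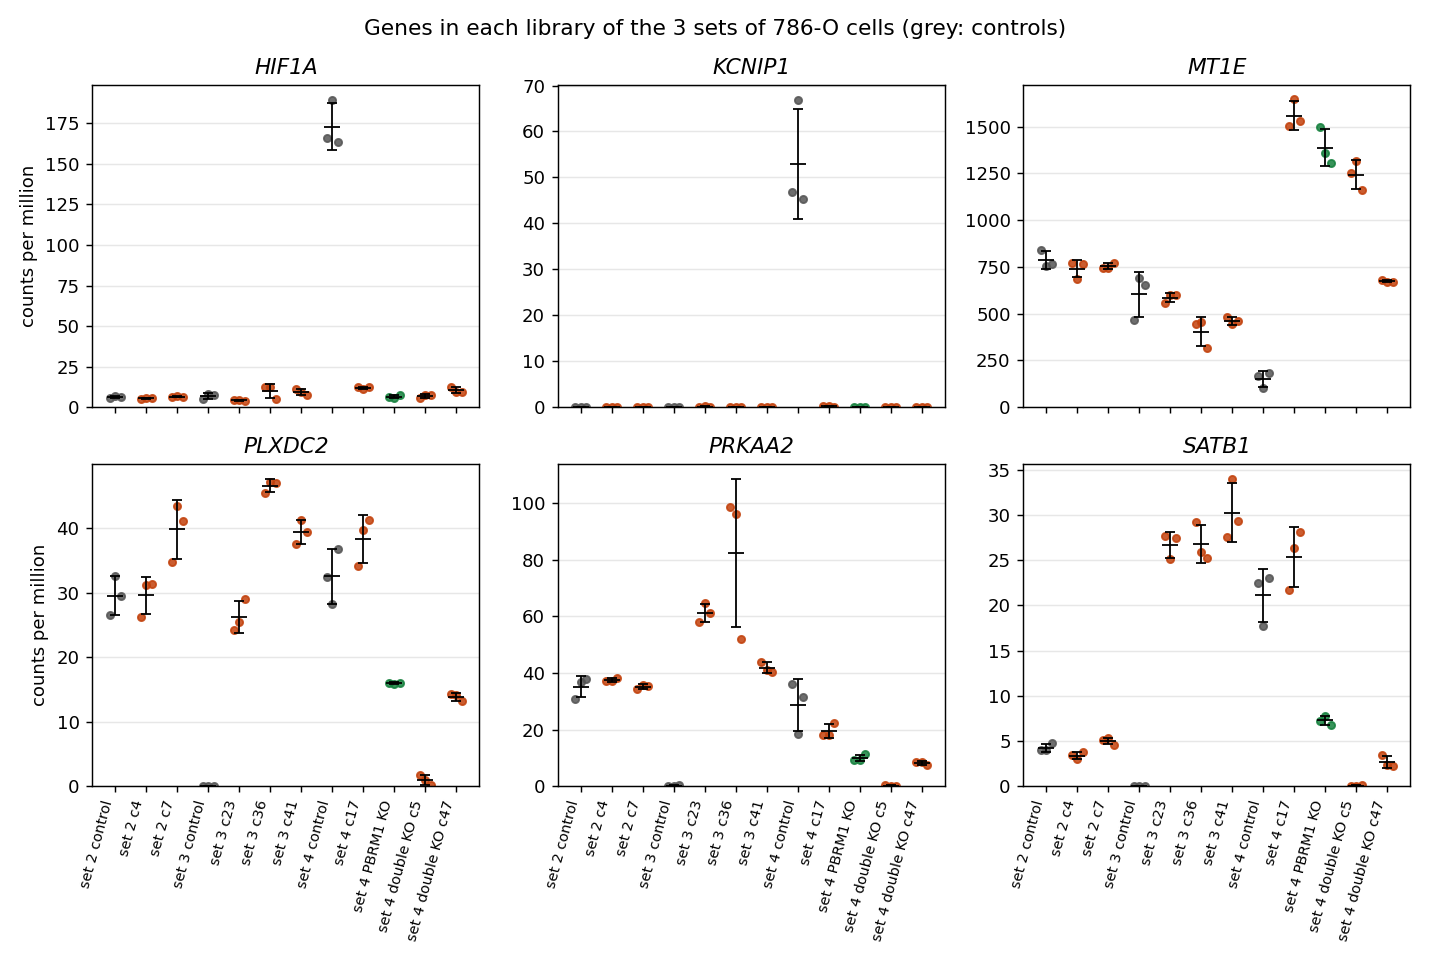
HIF1A, KCNIP1, MT1E, PLXDC2, PRKAA2 and SATB1 CPM in each library of the 12 groups of 786-O, controls in grey, mean ± SD. HIF1A is at 173 ± 14 in the set 4 control and at most 12.0 ± 0.53 elsewhere; the genes were chosen after the values were seen.

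The ADIRF-AS1 clones of set 2, c4 and c7, changed the fewest genes in 786-O, with the same genes at the head of both. The Ras-like GTPase RRAD rose from 0.992 ± 0.16 to 46.8 ± 0.65 CPM in c4 and to 46.2 ± 2.2 in c7 (n = 3; log2 fold change 5.54 ± 0.13 in c4, edgeR adjusted p = 9.2e-15). The iron-storage light chain FTL rose from 667 ± 24 to 2468 ± 45 in c4 (1.89 ± 0.05) and by 1.81 ± 0.05 in c7, and the tubule-shaping protein ATL3, the lysosomal sulfatase GALNS and its direct neighbour TRAPPC2L also rose. The chaperone HSPH1 fell in c4 from 560 ± 29 to 109 ± 5.1, the transporter SLCO4A1 fell by 0.99 ± 0.10 in c4 and 1.14 ± 0.10 in c7, and cyclin D1 (CCND1) fell by 0.54 ± 0.04 and 0.58 ± 0.04. The type VI collagen chains COL6A2 and COL6A1 rose in c4 (2.05 ± 0.10 and 0.34 ± 0.06). Of 26 immediate early genes, 6 fell in c4 and 4 in c7 and none rose (adjusted over the list alone, 1 rose and 9 fell in c4, and 0 and 11 in c7), with PHLDA1 at -0.77 ± 0.07 and -0.82 ± 0.07 and IER3 at -0.32 ± 0.08 and -0.35 ± 0.08. Of 36 HIF targets, 6 fell in c4 and 4 in c7. edgeR called 240 genes higher and 141 lower of 14687 in c4, and 156 and 105 in c7. With 1 library left out the totals ran from 124 to 501 in c4 and from 138 to 417 in c7. The camera test put immediate early genes lower in both (adjusted p = 2.5e-06 in c4, with adjusted p = 0.13 with an estimated correlation, and 3.0e-06 in c7, with adjusted p = 0.092 with an estimated correlation), and no list held in either clone with an estimated correlation.

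Cell-cycle genes fell in the set 3 clones, most of all in c41. Of 53 G2/M genes, 51 fell in c41 and none rose (median log2 fold change -1.49), with the proliferation marker MKI67 at -2.49 ± 0.13 and the centromere chaperone HJURP at -2.29 ± 0.11; 36 fell in c23 (median -0.66) and 13 in c36, where 1 rose. Of 39 S-phase genes, 36 fell in c41, 26 in c36 (CLSPN -0.93 ± 0.10, HELLS -1.0 ± 0.13) and 15 in c23, with none higher in any of the 3. Targets of p53 moved the other way: 16 of 33 rose in c41 and 4 fell, among them the cell-cycle inhibitor CDKN1A (1.56 ± 0.12) and MDM2 (1.38 ± 0.13), and CDKN1A rose in c23 and c36 too (1.19 ± 0.12 and 1.26 ± 0.12). Of 36 HIF targets 21 fell in c41 and 1 rose, including NDRG1 (-1.43 ± 0.09), and the hormone STC1 went from 69.0 ± 5.2 to 0.0697 CPM. The matrix peroxidase PXDN fell in c23, c36 and c41 (-7.92 ± 0.62, -7.73 ± 0.61 and -8.09 ± 0.63), and the invariant chain CD74 rose by 4.82 ± 0.22, 4.17 ± 0.22 and 5.97 ± 0.22. Both also differed widely between controls. By library total PXDN was at 112 CPM in the set 3 control, 34.5 in the set 2 control and 0.96 in the set 4 control. CD74 was at 0.92, 20.6 and 4.62 in the same order. SATB1, the scaffold protein USH1C, PLXDC2 and PRKAA2, near 0 in the set 3 control, stood at 27.5 ± 1.3, 25 ± 2.3, 27 ± 2.6 and 63.1 ± 3.8 in c23. ANKRD1, a YAP target, fell in all 3 (-2.58 ± 0.16, -2.64 ± 0.16 and -4.03 ± 0.18).

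edgeR called 2080 genes higher and 2185 lower of 15360 in c23, 1593 and 1756 in c36, and 2645 and 2818 in c41. With an estimated correlation, camera kept S-phase genes in c36 (adjusted p = 0.016) and G2/M, S-phase, HIF, p53 and locus genes in c41 (adjusted p = 0.0103, 0.00678, 0.0103, 0.0189 and 0.0292). Without the libraries that stand apart, the HIF (0.0613) and locus (0.0676) calls of c41 were lost, and S-phase genes and p53 targets held in c23 (0.0397 each). With all libraries nothing held in c23: G2/M genes went from 2.5e-10 to adjusted p = 0.0926 with an estimated correlation, p53 targets (14 of 33 higher, 3 lower) to adjusted p = 0.0639 with an estimated correlation, and integrins and cadherins (9 of 25 lower, 1 higher, ITGB2 -4.01 ± 0.38) to adjusted p = 0.169 with an estimated correlation. NF-kB targets in c23 (8 of 21 higher, 1 lower) were called at 0.0418, with adjusted p = 0.135 with an estimated correlation. The G2/M call of c36 was lost as well (adjusted p = 0.41 with an estimated correlation). The renal epithelial list in c41 (7 of 13 higher, 2 lower) was called by camera, with adjusted p = 0.143 with an estimated correlation. Neighbours of the ADIRF-AS1 locus, a list that holds ADIRF-AS1 and ADIRF themselves, fell in 7 of 10 measured genes in c41 (median -1.01) and in 5 of 10 in c36 (adjusted p = 0.091 with an estimated correlation). Adjusted over the list alone, S-phase genes counted 33 lower in c36 and 19 in c23, and G2/M genes 38 lower in c23.

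Clone c17 of set 4 raised metal-response and p53 genes and lowered ribosomal protein, collagen and HIF genes. Of 6 metallothionein genes 5 rose and 1 fell (median 2.68), with MT1E going from 160 ± 43 to 1566 ± 73 CPM (3.29 ± 0.15) and MT2A rising by 2.07 ± 0.09, and the zinc exporter SLC30A1 rose by 3.67 ± 0.19. These are close copies of one another, so counts within the family are uncertain, and MT1E in the set 4 control was below that of the other controls. Of 83 ribosomal protein genes 53 fell and 1 rose (RPL32 -1.02 ± 0.09). HIF1A fell from 184 ± 20 to 12.0 ± 0.56 (-3.94 ± 0.15), a level near that of the controls of sets 2 and 3, and 15 of 36 HIF targets fell and 3 rose. Of 16 collagens 8 fell and none rose, with COL6A3 going from 89.0 ± 20 to 3.92, and the matrix protease MMP2 fell by 2.35 ± 0.18. The secretory kinase FAM20C fell from 107 ± 41 to 0.148. By library total it was at 100 in the set 4 control and at 8.51 and 14.2 in the controls of sets 2 and 3. The set 4 control thus stood apart for this gene too. Of 32 p53 targets 18 rose and 4 fell (CDKN1A 1.46 ± 0.14, GDF15 1.73 ± 0.11), and 11 of 28 cholesterol synthesis genes rose and 2 fell (INSIG1 2.03 ± 0.12, MSMO1 1.51 ± 0.10, HMGCS1 1.11 ± 0.11). Adjusted over the list alone these counts were 20 higher and 4 lower for p53 targets, 12 and 3 for cholesterol synthesis, and 1 and 54 for ribosomal proteins. edgeR called 2062 genes higher and 2646 lower of 15448. With an estimated correlation camera kept ribosomal proteins, metallothioneins and p53 targets (adjusted p = 0.00937 each), cholesterol synthesis and locus genes (0.0207 each, the locus list again holding ADIRF-AS1 and ADIRF), HIF targets (0.0215), matrix glycoproteins (0.0366), and collagens and S-phase genes (0.0482 each), and lost histones (7 of 17 higher, 1 lower; adjusted p = 0.0983 with an estimated correlation) and oxidative phosphorylation (25 of 83 lower, 5 higher; adjusted p = 0.0983 with an estimated correlation). Without set 4 control 2 the collagens (0.138) and S-phase genes (0.103) of c17 were lost too.

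With the 6 ADIRF-AS1 clones of 786-O taken as the replicates, edgeR called no gene, though ADIRF-AS1 was lower in all 6. ADIRF-AS1 averaged -3.08 ± 0.43 over the clones, with an edgeR adjusted p of 0.760, and ADIRF averaged -3.10 ± 1.18. edgeR called 0 of 17978 genes, with 1066 at an unadjusted p under 0.05 where 898.9 would be expected with no effect, and DESeq2 called 11. S-phase genes (39, median -0.38), G2/M genes (53, median -0.27), HIF targets (36, median -0.18) and p53 targets (33, median 0.25) were called by camera with 0 genes called in each (adjusted p = 4.0e-09, 5.4e-05, 0.00034 and 0.00034). None held, with adjusted p = 0.67, 0.93, 0.67 and 0.67 with an estimated correlation. The fifth list called was the locus neighbours (11 genes including ADIRF-AS1 and ADIRF, median -0.40; adjusted p = 0.67 with an estimated correlation). In simulated data with planted effects the same test called 71.6% of genes at 2-fold and 98.5% at 4-fold. The planted folds were the same in every clone. ADIRF-AS1, lower in all 6 clones though at low counts, was itself not called. The 0 calls therefore do not show that the clones share no change.

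Counted clone by clone, 200 genes were called higher and 334 lower in at least 4 of the 6 clones of 786-O, against a mean of 273.6 in total and a maximum of 319 when calls were shuffled within clones. ADIRF-AS1, ALDH1A1, METRNL and SLC4A4 were called the same way in all 6. The retinal dehydrogenase ALDH1A1 rose by 0.55, 0.48, 0.80, 1.45, 2.11 and 0.77 log2 units in c4, c7, c23, c36, c41 and c17, the secreted factor METRNL by 0.36, 0.22, 0.35, 0.73, 0.47 and 0.58, and the bicarbonate transporter SLC4A4 by 0.39, 0.38, 0.56, 1.43, 1.48 and 0.67. Another 25 genes were called in 5 of 6: STC1, the growth factor TGFA, the transglutaminase TGM2 and SLCO4A1 fell in all but c17, the junction protein CLDN1 in all but c36, and FTL rose in all but c36. PHLDA1 fell in 5 and rose in c17 (1.34). The genes of this paragraph were chosen after their values were seen, and shuffling treats clones that share a control as independent.

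The PBRM1 knockout had lower matrix, ribosomal protein and HIF1A RNA and higher cell-cycle and metallothionein RNA than the set 4 control. HIF1A fell from 184 ± 20 to 6.20 ± 0.94 CPM (n = 3 each; log2 fold change -4.89 ± 0.16, edgeR adjusted p = 4.5e-11), and the controls of sets 2 and 3 were also near this lower level. The matrix protease genes ADAMTS5 (35.5 ± 0.31 to 1.19 ± 0.15) and MMP2 (76.7 ± 21 to 8.42) fell, as did the collagen chains COL6A3 (-2.5 ± 0.17), COL6A1 (-2.01 ± 0.17) and COL6A2 (-1.81 ± 0.24), the kidney cadherin CDH6 (-1.86 ± 0.12) and the stress regulator NUPR1 (-3.67 ± 0.19). Of 49 matrix glycoproteins 28 fell and 6 rose (FN1 -0.66 ± 0.09), of 16 collagens 11 fell and 1 rose, and of 39 matrix enzymes 17 fell and 5 rose. Of 83 ribosomal protein genes 51 fell and 2 rose, with RPL32 going from 1002 ± 150 to 457 ± 11. Of 53 G2/M genes 37 rose and 1 fell (HMMR 1.78 ± 0.18, CENPF 1.34 ± 0.11), and of 39 S-phase genes 23 rose and none fell (RFC3 1.21 ± 0.13, CLSPN 0.95 ± 0.10). Of 6 metallothionein genes 5 rose and 1 fell (MT1E 3.08 ± 0.15, MT2A 1.77 ± 0.09), and SLC30A1 rose by 3.29 ± 0.19. By library total MT1E was at 1387 in the PBRM1 knockout, 151 in the set 4 control, and 787 and 602 in the controls of sets 2 and 3. COL6A3 was at 16.1, 84.1, and 8.31 and 6.38 in the same order. For both, the set 4 control thus stood apart from the other controls. COL6A1 went the other way, at 14.3, 52.8, and 73.2 and 148. The actin bundler LCP1 rose from 7.21 ± 1.9 to 69.7 ± 2.1, the adhesion molecule L1CAM by 3.84 ± 0.36, and the interferon-stimulated genes USP18, XAF1 and BST2 by 2.4 ± 0.10, 2.84 ± 0.18 and 1.63 ± 0.13.

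edgeR called 2700 genes higher and 2981 lower of 15448 in the PBRM1 knockout. Camera kept with an estimated correlation ribosomal proteins and S-phase genes (adjusted p = 0.00383 each), matrix glycoproteins and metallothioneins (0.0106 each), oxidative phosphorylation (33 of 83 lower, 2 higher) and matrix enzymes (0.0268 each), and collagens and G2/M genes (0.0287 each). Of these, collagens were lost without set 4 control 2 (adjusted p = 0.101 with an estimated correlation). Renal epithelial genes (6 of 14 lower, 1 higher) were called at 0.0447, with adjusted p = 0.0811 with an estimated correlation. Adjusted over the list alone the counts were 2 higher and 52 lower for ribosomal proteins, 38 and 2 for G2/M, 6 and 29 for matrix glycoproteins, 2 and 11 for collagens, and 2 and 35 for oxidative phosphorylation. The group is 1 PBRM1 knockout in 3 libraries, so a clone effect cannot be set apart from the loss of PBRM1. Nor can changes that belong to the set 4 control.

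Most lists that camera did not call in the PBRM1 knockout held genes in both directions. Interferon-stimulated genes had 14 of 43 higher and 10 lower (adjusted p = 0.241), HIF targets 8 of 36 higher and 12 lower (0.362), p53 targets 9 of 32 higher and 5 lower (0.216), and cholesterol synthesis 10 of 28 higher and 5 lower (0.275; median 0.19, mean -0.06). NF-kB targets had 5 of 26 each way (0.753), the integrated and unfolded protein responses 9 of 37 higher and 10 lower (0.850), NRF2 targets 5 of 24 higher and 8 lower (0.911), and immediate early genes 4 of 27 higher and 3 lower (0.936). TGF-beta and YAP targets had 3 of 28 higher and 11 lower (0.252), epithelial to mesenchymal genes 1 of 18 higher and 5 lower (0.381), integrins and cadherins 3 of 24 higher and 10 lower (0.0798), and antigen presentation 4 of 18 higher and 2 lower (0.275). SWI/SNF subunits had 6 of 27 higher and 2 lower (0.453), histones 4 of 17 higher and 1 lower (0.272), core clock genes 3 of 21 higher and 7 lower (0.312), and osteoblast genes 2 of 7 higher and 1 lower (0.483). Of the 7 measured locus neighbours 1 rose (0.911), of 4 leukocyte genes 2 fell (0.319), of 2 endothelial genes 1 rose with no test made, and no mitochondrially encoded gene was measured.

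The double knockouts c5 and c47, fitted as a mean, had lower matrix and ribosomal protein RNA and almost no STC1, LAYN or HTATIP2. STC1 fell from 34.8 ± 2.5 to 0.559 ± 0.45 CPM in the 6 double knockout libraries (log2 fold change -6.35 ± 0.17), the hyaluronan receptor LAYN (-7.18 ± 0.32) and the tumour suppressor HTATIP2 (-7.0 ± 0.18) fell as far, and the peptidase ANPEP was near 0. HIF1A (-4.49 ± 0.12), COL6A3 (-3.71 ± 0.14), MMP2 (-4.15 ± 0.16) and NUPR1 (-5.81 ± 0.18) fell, and CDH6 went from 227 ± 42 to 20.6 ± 13. For HIF1A and COL6A3 the set 4 control stood above the controls of sets 2 and 3. Of 83 ribosomal protein genes 63 fell and 1 rose (median -0.67), of 16 collagens 12 fell and 1 rose (median -1.67), of 49 matrix glycoproteins 28 fell and 7 rose, and of 14 renal epithelial genes 9 fell and 1 rose (median -1.85). Targets of p53 rose in 17 of 32 and fell in 5, cholesterol synthesis genes rose in 14 of 28 and fell in 4 (INSIG1 2.03 ± 0.11), and metallothioneins rose in 5 of 6. LCP1 rose to 307 ± 170, L1CAM by 4.95 ± 0.35 and USP18 by 2.99 ± 0.09. edgeR called 3308 genes higher and 3931 lower, 3169 and 3617 in c5 alone, and 2996 and 3485 in c47 alone. Camera kept ribosomal proteins (adjusted p = 0.00239 with an estimated correlation), collagens, oxidative phosphorylation, metallothioneins, matrix glycoproteins and renal genes (0.0279 each), p53 targets (0.0326), and cholesterol synthesis and matrix enzymes (0.0430 each), and lost G2/M genes (23 of 53 higher, 6 lower; adjusted p = 0.270 with an estimated correlation). Without set 4 control 2, which stands apart, collagens (0.0695), oxidative phosphorylation and renal genes (0.0648 each), p53 targets and matrix enzymes (0.0536 each) and cholesterol synthesis (0.0695) were lost with an estimated correlation.

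Against the PBRM1 knockout, the double knockouts had lower cell-cycle and higher inflammatory RNA. Of 53 G2/M genes 18 fell and of 39 S-phase genes 21 fell, with none higher (CCNA2 -0.63 ± 0.09, KIF11 -0.74 ± 0.11, HELLS -0.74 ± 0.10), and adjusted over the list alone 23 and 25 fell. Of 26 NF-kB targets 10 rose and none fell (ICAM1 1.04 ± 0.10), and the acute-phase gene SAA1 rose by 1.51 ± 0.11. LAYN (-7.50 ± 0.31), HTATIP2 (-5.85 ± 0.19), the vesicle GTPase RAB31 (-5.67 ± 0.22) and STC1 (13.1 ± 2.1 to 0.559 ± 0.45) fell most, and the lectin CLEC4E (2.00 ± 0.16), LCP1 (1.94 ± 0.15) and ACACB (1.75 ± 0.12) rose. edgeR called 882 genes higher and 1340 lower in the double knockouts against the PBRM1 knockout, 2222 in all, with 1241 in all without 1 PBRM1 knockout library and 3839 without the libraries that stand apart. With an estimated correlation S-phase genes held at adjusted p = 0.000471, G2/M, NF-kB, ribosomal (14 of 83 lower, 1 higher), cholesterol (7 of 28 higher, 1 lower), renal (5 of 14 lower, 1 higher) and p53 lists (6 of 32 higher, 1 lower) at 0.0258, and locus genes (3 of 7 lower, ADIRF-AS1 and ADIRF among the 7) at 0.0323. Osteoblast genes (4 of 7 lower) were lost, with adjusted p = 0.0501 with an estimated correlation. Without set 4 control 2 in the fit of the set, S-phase genes alone held, and the other 7 lists ranged from 0.0536 for p53 targets to 0.121 for locus genes with an estimated correlation.

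Against clone c17, the double knockouts differed in more genes than they did against the PBRM1 knockout. The repair enzyme MGMT rose from 1.61 to 63.7 ± 16 CPM and the collagen chaperone SERPINH1 from 2.03 to 61.9 ± 19, the NF-kB inhibitor TNFAIP3 rose by 2.27 ± 0.14, and LAYN (-8.90 ± 0.29), STC1 (-6.29 ± 0.17), ADAMTS5 (-6.05 ± 0.15) and CDH6 (-2.90 ± 0.10) fell. Of 83 ribosomal protein genes 36 fell and 2 rose, of 14 renal epithelial genes 8 fell and 2 rose (median -0.91), and of 39 S-phase genes 14 rose and 3 fell. edgeR called 2351 genes higher and 2505 lower. Those 3 lists held with an estimated correlation (adjusted p = 0.029 each), and G2/M genes (20 of 53 higher, 1 lower) did not (adjusted p = 0.15 with an estimated correlation). All 3 were lost without set 4 control 2 in the fit (adjusted p = 0.125 each with an estimated correlation).

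Against the set 4 control, the double knockouts differed from the sum of c17 and the PBRM1 knockout in many genes. Metallothioneins were the only list whose departure from the sum held with an estimated correlation: 5 of 6 were lower than the sum and 1 higher (median -3.01; camera adjusted p = 2.1e-05, and adjusted p = 0.0131 with an estimated correlation), with MT1E at -3.88 ± 0.19, MT2A at -2.45 ± 0.12 and SLC30A1 at -4.33 ± 0.23. HIF1A (4.34 ± 0.21), COL6A3 (3.29 ± 0.24), CTHRC1 (4.91 ± 0.25) and LOXL1 (3.01 ± 0.18) were above the sum and STC1 (-4.88 ± 0.25) below it. For MT1E and HIF1A the set 4 control was apart from the controls of sets 2 and 3, and both single knockouts and both double knockout clones lay on the same side of the set 4 control. G2/M genes (15 of 53 below the sum, 1 above), NF-kB targets (11 of 26 above, 1 below), ribosomal proteins (29 of 83 above, 2 below) and matrix glycoproteins (18 of 49 above, 6 below) were called by camera and lost, with adjusted p = 0.187, 0.117, 0.117 and 0.117 with an estimated correlation. edgeR called 1566 genes above the sum and 1486 below it. The comparison rests on 1 group for each single loss (clone c17 and the PBRM1 knockout, for which the labels name no clone) and on the set 4 control. It therefore cannot set an interaction of the losses apart from that control.

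Across genes, changes in the PBRM1 knockout correlated only weakly with those in ADIRF-AS1 clones that had other controls. Over 14073 genes, the log2 fold changes of the PBRM1 knockout and the mean of the 5 clones of sets 2 and 3 had a Pearson r of -0.109 (covariance -0.0426, Spearman -0.0732). Clone c17, measured against the same control libraries as the PBRM1 knockout, gave r = 0.619 and a covariance of 0.380 over the same 14073 genes. Over the 15448 genes of set 4 it gave r = 0.70, with a covariance of 0.80 where chance sharing of the control gave 0.104 in simulations. The simulations cover the spread between control libraries, and not control cells that themselves stand apart. ADIRF-AS1 clones of the same set had r between 0.578 and 0.814 (4 pairs, against about 0.50 simulated from shared controls), and clones of different sets had r between -0.100 and 0.188 (11 pairs, median 0.0182). Clones with the same target were thus also weakly related between sets. The r between sets therefore cannot tell whether the losses of PBRM1 and ADIRF-AS1 act alike. Genes are not independent replicates, so no p value goes with these correlations.

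**Figure D3:**
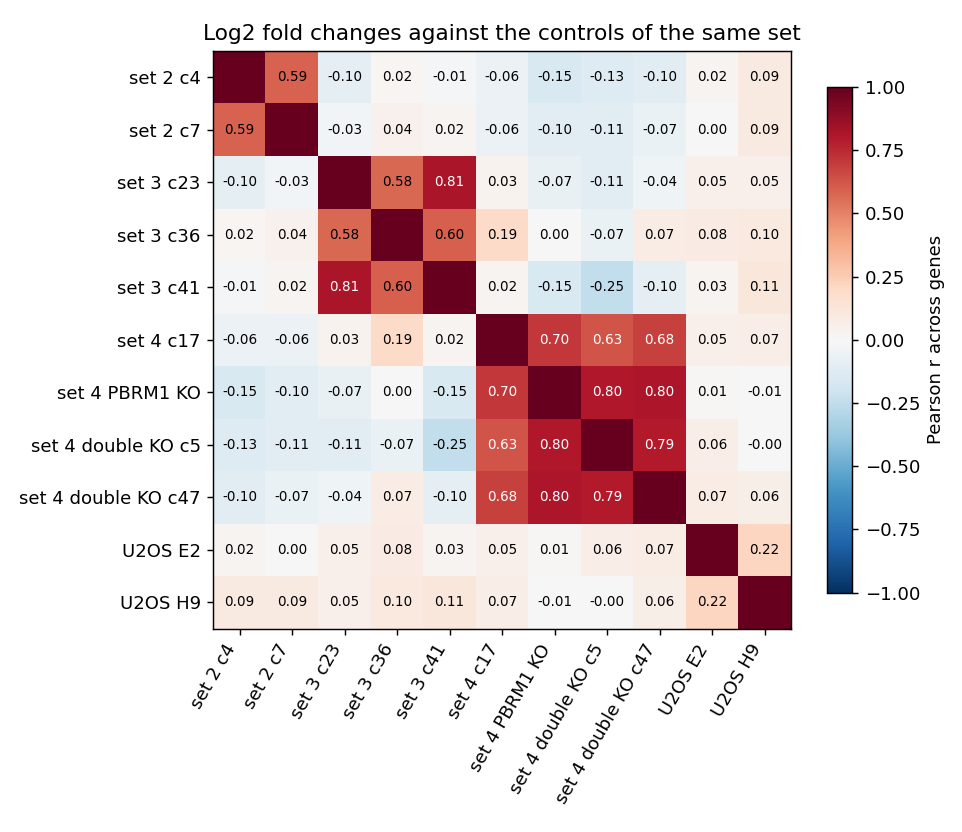
Pearson r between the log2 fold changes of 11 knockout comparisons. ADIRF-AS1 clones of 786-O from the same set reach 0.578 to 0.814, and ADIRF-AS1 clones from different sets -0.100 to 0.188.

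In U2OS, p53 targets were higher in the ADIRF-AS1 knockout clones, and most changes were under 2-fold. CDKN1A rose from 366 ± 32 to 507 ± 79 CPM (0.46 ± 0.03), with n = 13 libraries of the control line and 26 of E2 and H9 together. The ribonucleotide reductase subunit RRM2B rose by 0.37 ± 0.03, MDM2 by 0.24 ± 0.03 and the stress gene SESN2 by 0.34 ± 0.05. Libraries of a line are its time points, so standard errors and p values in U2OS cover the spread within lines. They do not cover the spread between lines. Of 31 p53 targets 15 rose and none fell, and adjusted over the list alone 17 rose and 4 fell. Mitotic genes fell, with KIF11 at -0.53 ± 0.06 and AURKA at -0.44 ± 0.06, in 22 of 53 G2/M genes with 1 higher, and 14 of 39 S-phase genes fell with 1 higher. Of 82 ribosomal protein genes 29 fell and 4 rose (RPS21 -0.59 ± 0.04). The metalloprotease ADAM12 (0.98 ± 0.12) rose, and ITGB2 (-1.08 ± 0.08), S100A4 (-0.89 ± 0.08), STC1 (-0.83 ± 0.11) and the immediate early gene IER2 (-0.65 ± 0.04) fell. The zinc-finger gene ZFP64 fell from 62.5 ± 7.0 to 37.6 ± 6.3 and the SWI/SNF ATPase SMARCA4 by 0.52 ± 0.05, mostly in E2 (-0.95 ± 0.06). The circadian repressor PER2 fell by 0.39 ± 0.12 (edgeR adjusted p = 0.0129). Several of these genes sit in runs of neighbouring genes that moved together: KIF11 in 77 genes from ANXA11 to OGA with a median of -0.54 in H9, SMARCA4 in 97 genes from ATG4D to SSBP4 with a median of -0.82 in E2 and -0.03 in H9, AURKA and RPS21 in 79 genes from ZSWIM1 to TCEA2 with -0.44 in H9, and ZFP64 and STX16 in a run lower in both clones (gene order of GRCh38.p14).

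edgeR called 1505 genes higher and 1795 lower of 15697 in U2OS, of which 26 and 74 passed 2-fold, and called 1090 in all with no time term in the fit. Camera kept p53 targets (adjusted p = 0.0169 with an estimated correlation) and lost G2/M, ribosomal and S-phase genes (each with adjusted p = 0.581 with an estimated correlation) and locus neighbours (1 of 9 higher, 4 lower, ADIRF-AS1 and ADIRF among them; adjusted p = 0.128 with an estimated correlation). Core clock genes were not called (3 of 21 lower, none higher; adjusted p = 0.917). Of 26 SWI/SNF subunits 6 fell and none rose (0.0531).

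Clones E2 and H9 moved cholesterol synthesis in opposite directions. Of 27 cholesterol synthesis genes 17 rose and 1 fell in E2 (median 0.23; HMGCS1 0.53 ± 0.04, SQLE 0.34 ± 0.04), and 19 fell and none rose in H9 (median -0.26; HMGCS1 -0.43 ± 0.04, SCD -0.95 ± 0.05). In H9, 56 of 82 ribosomal protein genes fell and 2 rose (camera, adjusted p = 0.0934 with an estimated correlation), 17 of 35 HIF targets fell and 1 rose (adjusted p = 0.0778 with an estimated correlation), and MT1E and MT2A rose by 0.35 ± 0.03 and 0.39 ± 0.04, where MT2A fell by 0.32 ± 0.04 in E2. CDKN1A rose in both (0.60 ± 0.04 and 0.31 ± 0.04). edgeR called 2382 genes higher and 2297 lower in E2 and 1611 and 2057 in H9. Of these, 387 were higher in both, 498 lower in both and 658 in opposite directions. Independent calls would give 244, 301 and 548, which does not allow for the control libraries that the clones share, so the excess cannot be read as agreement. The clones' effects had r = 0.216 with a covariance of 0.0262, where sharing the control alone gave 0.50 and 0.00954 in simulations. With the control libraries split so that the clones shared none, the observed r was 0.0320 and 0.0553 in the 2 splits (covariance 0.0032 and 0.0057). With an estimated correlation camera kept cholesterol synthesis (adjusted p = 0.0386), p53 targets (14 of 31 higher, 2 lower; 0.0113), locus neighbours (4 of 9 lower; 0.00106) and metallothioneins (3 of 4 higher; 0.0252) in H9. No list held in E2, where cholesterol synthesis had adjusted p = 0.32 with an estimated correlation. Each clone is 1 line, so clone and knockout effects cannot be set apart within it.

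**Figure D4:**
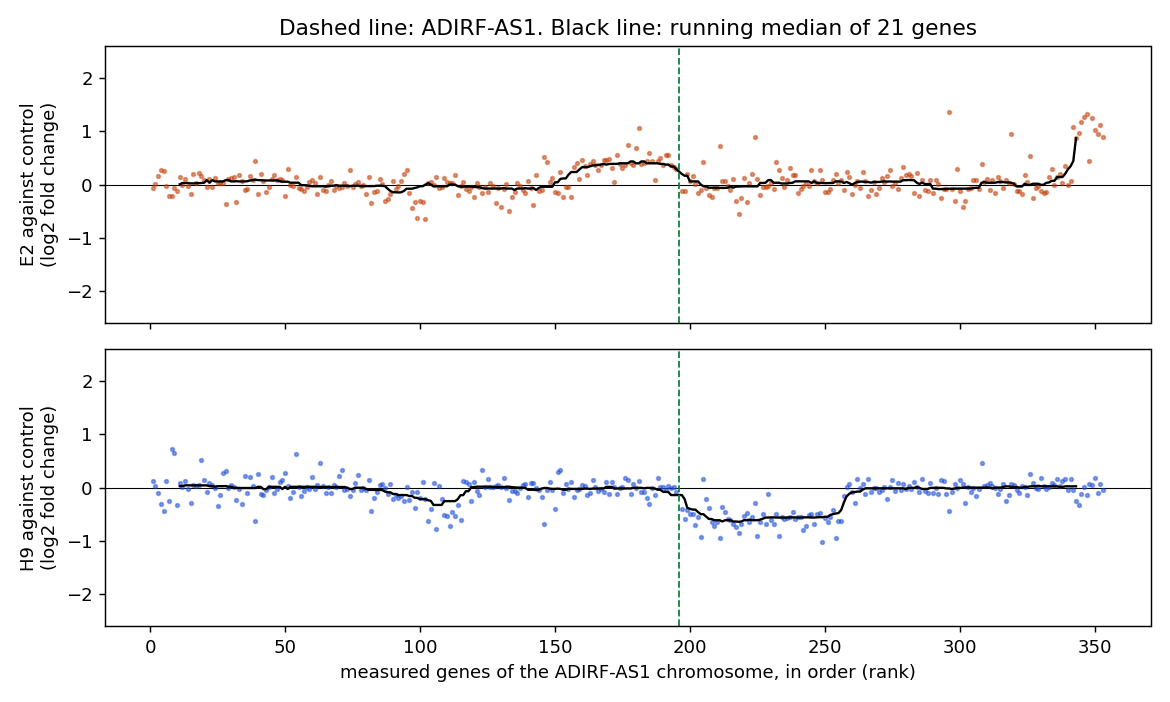
Log2 fold change of E2 and H9 along the measured genes of the chromosome that carries ADIRF-AS1, with the running median of 21 genes and a dashed line at ADIRF-AS1. The run from DNAJB12 to ATAD1 has a median of 0.37 in E2, and that from ANXA11 to OGA has -0.54 in H9.

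PER2, TEF and NR1D1 followed a 24 h course in the U2OS control, adjusted over the list alone, and CLOCK, RORA, CSNK1D and CSNK1E were not called. In the control PER2 had a log2 amplitude of 1.38 ± 0.34 with a peak at 8.59 ± 0.91 h and ran from 0.971 to 17 CPM, the output factor TEF had 1.32 ± 0.32 with a peak at 7.56 h, and the repressor NR1D1 had 1.09 ± 0.30 with a peak at 3.37 h. BMAL1, which peaks opposite to PER2, had 0.74 ± 0.37 at 18.7 h and was not called in the control (edgeR p adjusted over the list alone 0.117). ADIRF-AS1 had 0.79 ± 0.27 in the control with a peak at 8.36 h (1.31 to 8.59 CPM; edgeR unadjusted p = 0.0175). Of 21 core clock genes measured, 10 were rhythmic in the control, 9 in E2 and 6 in H9 adjusted over the list alone, PER2 in the control at 0.00650. Adjusted over all 15697 genes, edgeR called 0 genes in the control, 0 in E2 and 1 in H9 (ITGB1P1), with 557, 506 and 680 at an unadjusted p under 0.05 where 784.85 would be met by chance, and limma-voom called 0 in each. In simulated data the test called 79.1% of planted rhythms at a log2 amplitude of 0.5 and 100% at 1. Those were pure 24 h waves on flat genes, so the shares need not hold for the real series. There PER2, at 1.38 in the control, was not called over all genes (edgeR adjusted p = 0.696). From 12 h on, 8, 12 and 10 of 15876 genes were called in the control, E2 and H9, 7 of them in all 3 lines. PER2 then had 1.63 ± 0.20 with a peak at 9.77 h (edgeR adjusted p = 8.6e-06), NR1D1 1.42 ± 0.23 at 4.15 h, TEF 1.62 ± 0.26 at 8.40 h, PER3 1.26 ± 0.25, CRY1 0.89 ± 0.16 at 12.9 h and the tissue plasminogen activator PLAT 0.45 ± 0.06 at 21.7 h. ADIRF-AS1 had 1.00 ± 0.23 at 9.62 h and was not called (adjusted p = 0.62).

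**Figure D5:**
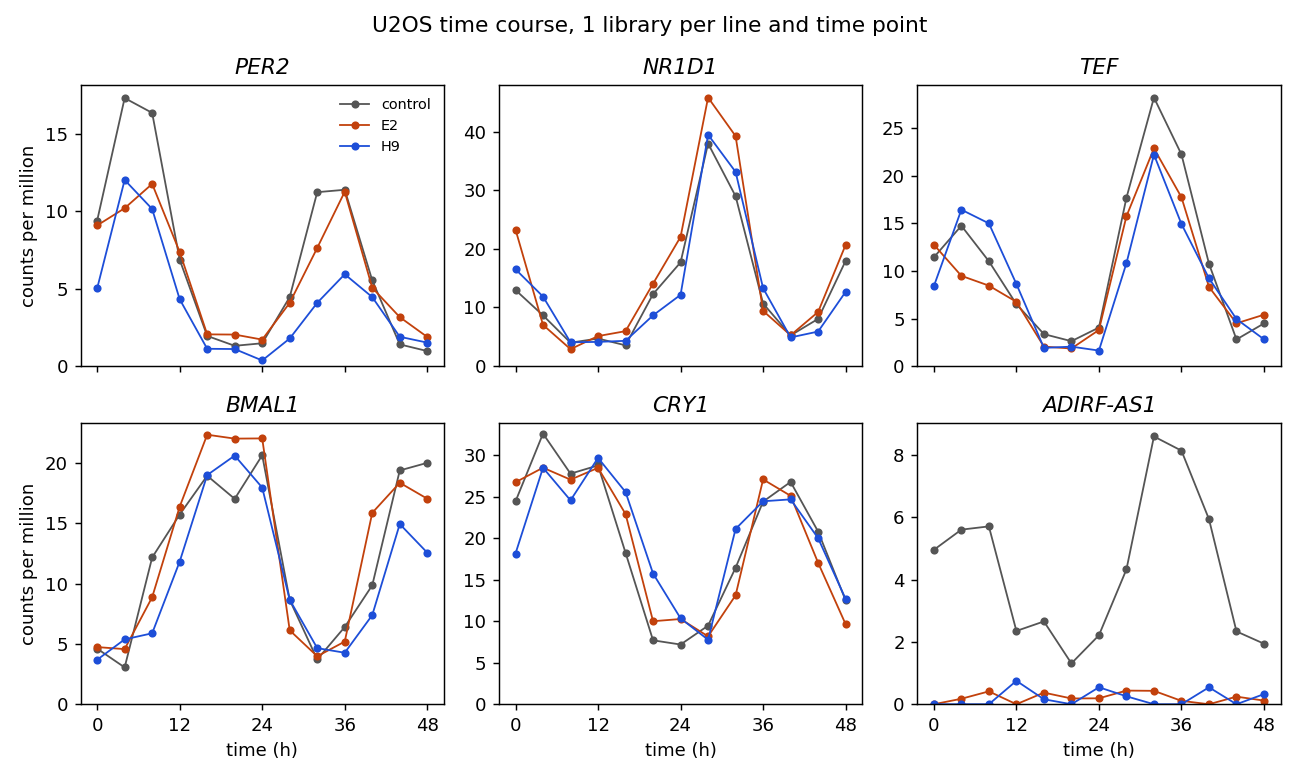
PER2, NR1D1, TEF, BMAL1, CRY1 and ADIRF-AS1 CPM from 0 to 48 h in the control, E2 and H9, with 1 library per line and time point. In the control PER2 peaks at 8.59 ± 0.91 h and ADIRF-AS1 ranges from 1.31 to 8.59 CPM.

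NR1D1 and TEF were rhythmic in the control, E2 and H9, adjusted over the list alone. Over all time points PER2 was called in the control and not in E2 (0.0526) or H9 (0.0704) in this way. From 12 h on the amplitude of PER2 was 1.63 ± 0.20 in the control, 1.17 ± 0.18 in E2 and 1.29 ± 0.19 in H9. PER2 was then called rhythmic in E2 and H9 too, adjusted over all genes (edgeR adjusted p = 0.00086 and 0.0034). Its rhythm did not differ between knockout and control over all time points (edgeR unadjusted p = 0.535). From 12 h on the difference had an edgeR unadjusted p of 0.0434 and was not called after adjustment. edgeR called 0 genes of 15697 for a difference in rhythm, with 337 at an unadjusted p under 0.05, and limma-voom also called 0. Against the control, E2 alone gave 2 genes (ITGB1P1 and MAGEL2). In simulated data planted differences were called for 68.7% of genes at a log2 amplitude of 0.5 and 98.5% at 1. These too were pure waves on flat genes, so the shares need not hold for the real series. With 1 library per line and time point the fit has no replicates within a time.

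The U2OS and 786-O effects of ADIRF-AS1 loss were weakly related. STC1 fell in U2OS and in 5 clones of 786-O and CDKN1A rose in U2OS and in c23, c36, c41 and c17. Over 14484 genes the mean effects had r = 0.114, and single clones of the lines had r between 0.0008 and 0.112 (12 pairs). Of the genes called the same way in at least 4 clones of 786-O, 35 were higher in both lines and 77 lower in both, where independent calls would give 17 and 35.1. Those expected counts take every gene as equally likely to be called, and opposite directions were not counted. Clones of a set also share a control. The excess thus cannot be read as a shared effect of ADIRF-AS1 loss.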

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

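The tests of correlation between sets, of set 3 without the libraries that stand apart, of ADIRF against ADIRF-AS1 and of a step at ADIRF-AS1 were chosen after the results were seen. In set 4 the interaction test of edgeR called 3052 genes, for which the double knockouts differed from the sum of c17 and the PBRM1 knockout, each taken against the set 4 control. That contrast holds 1 group for each single loss and a control that differs from those of the other sets, so the count cannot be put down to the 2 losses alone. In U2OS, a direct test between the clones called 6456 of 15697 genes (3500 higher in E2 and 2956 higher in H9, and 6334 with DESeq2). Cholesterol synthesis genes differed between E2 and H9 in that test (camera adjusted p = 9.91e-12, and adjusted p = 0.0396 with an estimated correlation): 23 of 27 were higher in E2 and 1 was lower, with HMGCS1 at 0.96 ± 0.04 and SCD at 1.14 ± 0.05. SCD lies in a run of genes lower in H9.

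Changes of the U2OS clones run in part along neighbouring genes, with 15.1% of the called genes of E2 and 7.60% of those of H9 inside such runs, among the 9005 genes placed in order (6.53% and 2.78% of all placed genes). A gene's log2 fold change correlated with the mean of its 10 neighbours at 0.506 in E2 and 0.414 in H9, where 1000 shuffles of gene order reached at most 0.0490. The change over time within the control gave 0.0682. That contrast sets early against late libraries of 1 line, which also differ in depth. It cannot decide whether neighbours share a regulation that differs between clones. At ADIRF-AS1 the mean change stepped from 0.47 ± 0.20 (20 genes before) to 0.03 ± 0.22 (20 after) in E2 and from -0.02 ± 0.12 to -0.53 ± 0.24 in H9, and as large a step was found at 0.580% and 0.469% of positions. A candidate explanation is a difference in copy number of chromosome segments, with a break at the site edited in ADIRF-AS1, which could raise or lower genes for reasons apart from the RNA. DNA was not measured, and segments that already differed between cells of the parent line stay open.

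Effects of 786-O clones are shared far more within a set than between sets, though 534 genes were called the same way in at least 4 of 6 clones. The highest correlation between clones of different sets was 0.188, which argues against ADIRF-AS1 loss as the main source of each clone's changes. Chance values of the shared controls are argued against by the lowest covariance in set 3 (0.659, where simulations reached 0.0827). In set 2 the covariance was 0.0653, where 20 simulations averaged 0.0294 and reached 0.0353. That argues against such chance values as its whole source, though they may supply part of it. It stays under the 2 times asked for in set 3. The 3 libraries that stand apart are argued against in set 3 by the lowest covariance without them (0.786, where simulations reached 0.0872). Controls that themselves differ from the other cells of the line are a candidate. The set 2 control was nearer to the knockouts than to the set's own control for 58.3% of the shared genes of set 3 and 78.2% of those of set 4. The remaining control was nearer for 66.4% and 53.7%, and both for 42.8% and 45.9%. These genes were picked because the set's own control lay apart from every knockout group, and no share expected from that choice alone was computed. The shares thus cannot decide the question, and part of each set's changes may belong to its control. Whether the controls differ by origin, handling or time in culture is not stated.

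ADIRF falls together with ADIRF-AS1. Reads of ADIRF-AS1 counted for ADIRF are argued against as the whole source by c23, which kept 62.3% of ADIRF and 11.1% of ADIRF-AS1. Removal of DNA at the start of both genes could lower both: ADIRF was called lower in 8 of 10 clones, though other genes nearby did not keep their level in all of them (of the nearest 20, 19 were lower in c41, 17 in c36 and 14 in H9). The edited bases are not given, so this and an effect of the RNA on ADIRF cannot be told apart.

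With the libraries of a comparison split at random, 10 splits of 3 against 3 cannot give a share under 0.05: in each of c4 (381 genes, highest other split 0), c7 (261, 10), c23 (4265, 0), c36 (3349, 2), c41 (5463, 0), c17 (4708, 1) and the PBRM1 knockout (5681, 0) 1 of 10 splits, the real one, gave as many genes. The real split gave the most genes for the double knockout (7239 genes, 1 of 100 splits, highest other 5873) and for it against c17 (4856, 1 of 100, 3244). The same held for the interaction (3052, 1 of 100, 1197) and for U2OS (3300, 1 of 100, 1448). For the double against the PBRM1 knockout (2222, 2 of 100) another split gave more genes (2306). Splits take the libraries of a clone, or the time points of a line, as independent. They therefore cannot exclude chance differences between clones or lines. These splits show that libraries differ by group or line, and they cannot set the knockout apart from other differences between clones. Other splits of set 4 also call many genes, since they mix groups that differ strongly. Splits decide nothing for the test across clones (0 genes, reached by 24 of 24 splits, highest other 0), for rhythms (0, 40 of 40, 392) or for differences in rhythm (0, 40 of 40, 1), since every split reaches a count of 0. Some orders of the time points gave up to 392 genes against 0 for the real order in the control, which points to a structure of the samples over time, and its source was not tested.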

How the results depend on the processing

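Clone c4 (381 genes) moved with no filter (810) and fell to 163, 172, 162, 124 and 160 without set 2 control 1, control 2 or c4 library 1, 2 or 3, and clone c7 (261 genes) moved with no filter (584), to 138 and 168 without set 2 control 2 or 3, and to 417, 139 and 164 without c7 library 1, 2 or 3. Over all single libraries left out, calls ran from 124 to 501 in c4, 138 to 417 in c7, 3137 to 3766 in c23, 2614 to 4265 in c36, 4325 to 4914 in c41, 3594 to 5061 in c17, 4517 to 5912 in the PBRM1 knockout, 6788 to 7445 in the double knockout (5912 to 7400 in c5, 5504 to 6905 in c47), 3709 to 4478 for the double knockout against c17, 2266 to 3650 for the interaction, 0 to 0 across clones and 416 to 749 for genes in at least 4 of 6 clones. The double knockout against the PBRM1 knockout (2222 genes) ran from 1241 to 1953, with 1296, 1241 and 1332 without PBRM1 knockout library 1, 2 or 3, and gave 3839 without the 3 libraries that stand apart. A fit with fewer libraries has less power by construction; otherwise the cause was not tested. The 3 libraries that stand apart, a choice made after seeing the data, kept every other count within 1.5 times.

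The test across clones called 0 genes, and called 11 with DESeq2, 1 with no filter and 2 without set 2. Fits to the 27 libraries called 154 in limma-voom with clone as a random block, and 1551 in edgeR ignoring clone, which by construction takes libraries of 1 clone as independent. The U2OS counts fell with no time term, to 1090 for the mean, 1926 in E2, 1127 in H9 and 196 in both clones the same way (387 up and 498 down with it), and the latter to 537 with a harmonic in place of the time factor. Rhythm calls in the control (0) became 7 with a period of 26 h, 8 without 0, 4 and 8 h, 30 for the mean of the 3 lines and 102 for that mean without 0, 4 and 8 h, the last 2 chosen after seeing the data. In E2 (0) they became 4 at 26 h and 12 without 0, 4 and 8 h, and in H9 (1) 4 at 26 h, 10 without 0, 4 and 8 h, and 0 with no trend, with limma-voom and with a filter of 10 CPM. The difference in rhythm (0) gave 2 with E2 alone, and the correlation of U2OS with 786-O (0.114) was 0.0644 with E2 alone. The correlation of the PBRM1 and ADIRF-AS1 knockouts ran from -0.132 to -0.0874 with 1 clone left out and was -0.121 without the 3 that stand apart. Calls of lists (127 by camera) fell to 49 with an estimated correlation and rose to 256 with fry. Some also changed without the 3 libraries that stand apart. The cause was not tested for these.

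Without those 3 libraries, camera at the preset correlation no longer called renal genes in the PBRM1 knockout (adjusted p = 0.0813) or c41 (0.0635), locus neighbours in c36 (0.0675) or in the double against the PBRM1 knockout (0.0658), G2/M genes in c36 (0.0703) or NF-kB targets in c23 (0.0709), and 8 other lists became called. With an estimated correlation, the lists held in the sets concerned went from 44 to 25 without them, and the cause was not tested. Of 1395 values of named genes, tried in 16912 alternatives, 16345 stayed on their side of the threshold, 557 were weaker, 10 stronger and 0 reversed. Another scaling moved the median log2 fold change by at most 0.015. Low depth limits ADIRF-AS1 itself, with 8 to 104 counts per library in the U2OS control.

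Replicate numbers do not pair the libraries: deviations of libraries with the same number had a mean r of 0.008, 0.015 and -0.021 in sets 2, 3 and 4, and 4 of 9, 6 of 12 and 3 of 15 libraries correlated best with their own number. With a replicate block the counts were 309 in c4, 213 in c7, 4003 in c23, 2992 in c36, 5258 in c41, 4317 in c17, 5302 in the PBRM1 knockout, 6925 in the double knockout, 1885 and 4486 against the PBRM1 knockout and c17, 2676 for the interaction and 451 in at least 4 of 6 clones, and a replicate block over 27 libraries called 737 genes across clones.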

Other observations

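The acute-phase gene SAA1, the heat-shock protein CRYAB and the transporter SLC7A11 rose in some clones and fell in others. SAA1 rose from 1.64 ± 1.15 to 60.3 ± 4.3 CPM in c23, 36 ± 3.2 in c36 and 24.1 ± 2.7 in c41, fell in set 4 from 53.9 ± 8.7 to 29.1 ± 1.6 in c17 and 8.50 ± 0.19 in the PBRM1 knockout, and in U2OS rose in E2 (1.29 ± 0.10) and fell in H9 (-0.60 ± 0.11). CRYAB rose in c23, c36 and c41 (4.45 ± 0.25, 1.92 ± 0.27 and 4.78 ± 0.25) and fell in E2 (-1.73 ± 0.07). SLC7A11, which carries cystine, rose in c23 (2.03 ± 0.14) and fell in c17 (-1.93 ± 0.09). These genes were chosen after their values were seen.

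Of 83 oxidative phosphorylation genes 34 rose and 3 fell in c23 (median 0.36), and 33 rose and 6 fell in c41 (median 0.34), called by camera in both at the preset correlation and lost (adjusted p = 0.197 and 0.237 with an estimated correlation). In c36, 14 rose and 5 fell and camera made no call (adjusted p = 0.0804). Of 82 ribosomal protein genes 14, 16 and 20 rose in c23, c36 and c41 and 2, 2 and 3 fell (adjusted p = 0.347, 0.352 and 0.384 with an estimated correlation). In set 2, genes of the stress responses fell, 7 of 36 in c4 with none higher and 8 in c7 with 1 higher (adjusted p = 0.13 and 0.209 with an estimated correlation), and in H9 12 of 37 interferon-stimulated genes rose and 4 fell (adjusted p = 0.0625 with an estimated correlation). From 12 h on, the mitotic genes CDC20, CCNB1 and DLGAP5 were called rhythmic in E2 (amplitudes 0.31 ± 0.04, 0.40 ± 0.09 and 0.39 ± 0.04) and not in the control or H9, and no difference in rhythm was called for them.

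Clones of 786-O also had changes that ran along neighbouring genes. The correlation of a gene with its 10 neighbours was 0.153 in c4, 0.107 in c7, 0.289 in c41, 0.336 in c23, 0.344 in c36 and 0.326 in the PBRM1 knockout. A step as large as that at ADIRF-AS1 was found at 3.81% of positions for c41, 5.68% for c23, 9.2% for c17 and 43.8%, 48.7% and 47.8% for c4, c7 and c36, and at 2.5% for the PBRM1 knockout, in which ADIRF-AS1 was not the target. Of the 20 measured genes nearest to ADIRF-AS1, 19 were lower in c41 (mean -0.98, with 0 of 1000 random sets of genes as low) and 17 in c36 (mean -0.43, 3 of 1000), where 11, 13, 15 and 13 were lower in c4, c7, c23 and c17. Random sets ignore that neighbouring genes move together.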
